A study of Mus musculus with 6 samples.

How the data were processed

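The series holds 6 RNA-seq libraries of mouse aorta, 3 per group, made with a stranded total RNA kit and sequenced as paired ends, per the labels' protocols. The authors deposited 1 table with a whole-number count and an FPKM value per gene and library, with gene identifiers, symbols, coordinates and KEGG terms, per the file headers. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the build GRCm38. Their versions and roles, the annotation release and the counting mode were not given in the sources used here. Deposited counts summed to 64556253 to 67859566 per library. Among counts below 60, 56.3% to 57.4% were even, and whether both reads of a pair were counted was not tested. If they were, sampling noise is larger than the totals imply. Nuclear copies of mitochondrial genes took 2.84% to 4.97% of counts, so reads with several matches appear to have been counted, and genes with near-identical copies are uncertain. Whether the counting used strand is not given, so overlapping antisense genes are uncertain too. The FPKM values, normalised to gene length and library size as the authors deposited them, were used only for 1 alternative.

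Of 32771 gene identifiers, 99.7% were in GENCODE M21, of which 100% lay on the same chromosome and 90.8% had the same start and end. Coordinates are those of the deposited table. No 2 libraries agreed within sampling noise (chi-square per degree of freedom from 40.1 for anti-CTHRC1 replicates 7 and 39 to 345.9).

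Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, robust dispersion and a quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 libraries entered without covariates, and 19241 genes were tested. CPM values are scaled by TMM, and standard errors were derived from the moderated F. The biological coefficient of variation was 0.397. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 34 lists, with an estimated correlation and fry as alternatives. KEGG terms were tested likewise. The table held no comparison by the authors, so none was summarised.

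The comparison, its alternatives, the 34 lists and the rule for named genes were set before the data were examined. That rule took Cthrc1, the 10 largest changes per direction among genes past the threshold with no overlap between groups, a mean of 1 CPM or more and a named symbol, up to 4 members with the smallest p in each list, and a fixed panel. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a mean of 5 CPM in 1 group, library sizes without mitochondrial and haemoglobin genes, a threshold of 0.10, a minimum log2 fold change of 1, and leaving out each replicate. Added after the data were seen were limma on log2(FPKM + 1) for genes of 1 FPKM or more, leaving out anti-CTHRC1 39 and IgG 14 together, an adipocyte covariate, DESeq2 leaving out each replicate, the gaps between lists leaving out each replicate, and the KEGG alternatives. A pseudocount alternative applied only to a table without counts and was not run.

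The edgeR step was tested on simulated counts for anti-CTHRC1 against IgG with 200 changed genes among 18627. It recovered 37% of genes changed 2-fold and 77% of those changed 4-fold, with 8 false calls. In a second simulation camera called the 1 moved list in its direction and 0 others. Genes were simulated independently of each other, so this cannot show how often lists pass wrongly when their members vary together. In the data the estimated correlation was 0.4 for macrophage markers and 0.97 for oxidative phosphorylation. The estimate of mixture shares returned 0.3 and 0.6 for simulated mixtures of IgG replicates 18 and 20 made with those shares. These were exact mixtures with sampling noise only, so the check does not show what the estimate returns for an unmixed library.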

Results

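RNA was measured in 6 libraries of aorta from wild-type mice that had all received AngII/BAPN, an infusion of angiotensin II with the lysyl oxidase inhibitor beta-aminopropionitrile that is used to produce aortic dissection in mice. In 3 libraries the infusion was combined with an antibody against CTHRC1, a secreted collagen triple helix repeat protein of activated fibroblasts, and in the other 3 with an isotype IgG. The comparison asks which transcripts differ in the aorta when CTHRC1 is targeted by antibody under AngII/BAPN. Total counts per library ran from 64556253 to 67859566, and 23716 to 26950 genes had at least 1 count. The labels number the libraries (anti-CTHRC1 replicates 5, 7 and 39, IgG replicates 14, 18 and 20) without saying that each came from a separate animal, so p-values measure the spread between these libraries only.

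Of the 6 libraries, 2 stood apart. Anti-CTHRC1 replicate 39 lay between replicates 5 and 7 in 93.3% of the 2271 genes in which these differed by more than 0.5 on the log2 scale. In other sets of 3 libraries this share reached 81.7%, for replicate 39 between replicate 7 and IgG replicate 20. In sets without replicate 39 it reached 73.3%. A mixture of 39% replicate 5 and 61% replicate 7 left a median difference from replicate 39 of 0.030 (log2) in genes of 100 to 1000 CPM, where replicates 5 and 7 differed by a median of 0.276. The spread within the antibody group is therefore measured on libraries that were not shown to be independent of each other, and the adjusted p-values treat them as 3 replicates. IgG replicate 14 held 288 genes at 4-fold or more above each other library with 1 CPM added to each value, against 1 to 3 such genes in the others. It also had the lowest mitochondrial share, 12.3% against 15.7% to 22.8%. On the first principal component, which took 42.9% of the variance, IgG replicate 14 scored 120.8 and IgG replicate 18 scored 51.0, and the other 4 libraries scored between -48.6 and -37.3.

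**Figure D1:**
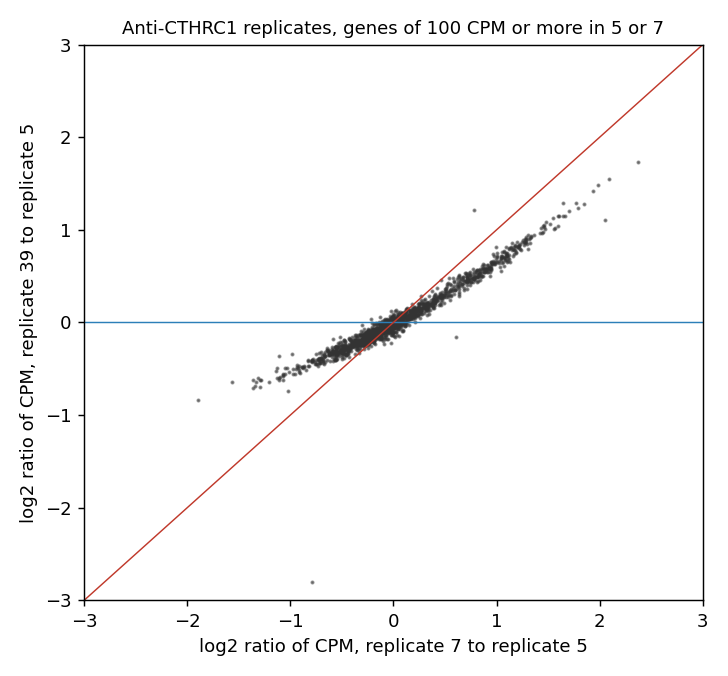
Each point is 1 of 1625 genes with 100 CPM or more in anti-CTHRC1 replicate 5 or 7, with the log2 ratio of replicate 7 to replicate 5 on the horizontal axis and of replicate 39 to replicate 5 on the vertical axis. The blue line is where replicate 39 would equal replicate 5 and the red line where it would equal replicate 7, and most points lie in a narrow band between the lines, with a few outside it.

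After the antibody, Spp1, the protease genes Adam8 and Mmp12 and the macrophage genes Mpeg1 and Trem2 were lower, and a smaller set of genes that includes the atrial muscle genes Myl7 and Myl4 and the adipocyte gene Lep was higher. Spp1, which encodes osteopontin, was at 28.5 ± 10.7 CPM after the antibody and 426 ± 202 CPM after IgG (mean ± SD, n = 3 each). It fell by 3.90 on the log2 scale (SE 0.45, adjusted p = 0.0344, edgeR quasi-likelihood test). Adam8, a membrane metalloprotease of leukocytes, fell by 3.11 (SE 0.22), and Mmp12, the macrophage elastase, fell by 3.11 (SE 0.32). In all, 20 genes were higher and 41 lower among 19241 tested, with absolute log2 fold changes from 0.69 to 4.64, and in each of the 61 genes the groups did not overlap. Across all tested genes the groups did not overlap in 4242, or 22%, where chance gives 10% for 3 independent libraries against 3 and 20% if replicate 39 always lies between replicates 5 and 7. Replicates 5 and 7 alone did not overlap with the IgG libraries in 26.9% of genes, where chance gives 20%.

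The count of 61 depended on single libraries. Without anti-CTHRC1 replicate 39 the edgeR test called 0 genes, with 1802 at an unadjusted p under 0.05, and DESeq2 on the same 5 libraries called 732. Without anti-CTHRC1 replicate 7 it called 0 (2054 unadjusted, DESeq2 930), without IgG replicate 18 it called 0 (2468 unadjusted, DESeq2 1012), and without anti-CTHRC1 replicate 5 it called 2 (3136 unadjusted, DESeq2 1964). Without IgG replicate 14 the edgeR count was 190 and without IgG replicate 20 it was 227. With replicates 39 and 14 both left out, edgeR called 0 genes, with 2056 at an unadjusted p under 0.05, and DESeq2 called 672. On all 6 libraries DESeq2 called 588 genes higher and 996 lower.

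Cthrc1 itself (ENSMUSG00000054196, chromosome 15, 39076932 to 39087121 on GRCm38) was at 265 ± 7.24 CPM after the antibody and 180 ± 69.8 CPM after IgG. Its log2 fold change was 0.56 (SE 0.30, adjusted p = 0.382, edgeR), which did not pass the threshold, although the groups did not overlap. Without IgG replicate 18, which had the lowest level (99.35 CPM), the log2 fold change was 0.27, and with the adipocyte list as a covariate it was -0.04. The level of the adipocyte list did not overlap between the groups, so here and below this covariate cannot separate fat from the antibody.

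Among genes with the largest falls, Spp1 lies on chromosome 5 (104435118 to 104441050), Mmp12 on chromosome 9 (7344381 to 7369499) and Adam8 on chromosome 7 (139978932 to 139992562). Angptl7, a secreted angiopoietin-like protein, fell by 2.92 (SE 0.32). Gcnt4, a glycosyltransferase, fell by 2.67 (SE 0.33), and AA467197 fell by 2.59 (SE 0.27). Immune receptor genes were Cd300lf, which fell by 2.68 (SE 0.28), and Havcr2, which encodes TIM-3 and fell by 2.41 (SE 0.31). Serpina3g fell by 2.72 (SE 0.24) and Bcl2a1b fell by 2.36 (SE 0.23), but both belong to families of near-identical copies between which reads could have been split, so these values are uncertain.

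Macrophage markers were lower as a group. Of 20 tested, 18 had a negative log2 fold change, with a median of -0.85, and the list passed camera with an adjusted p of 5.44e-08. With an estimated correlation between genes the adjusted p was 0.662. Members past the threshold over all genes numbered 2, and 13 passed when adjusted over the list alone. Mpeg1, which encodes the pore-forming perforin-2 of macrophages (chromosome 19, 12460779 to 12465283), was at 43.5 ± 2.15 against 186 ± 33.5 CPM, and Trem2, a lipid-sensing receptor of macrophages, was at 9.56 ± 0.85 against 27.3 ± 2.11 CPM. Gpnmb (adjusted p = 0.0706) and Itgam (adjusted p = 0.0869) did not pass in edgeR on all 6 libraries. Both passed in DESeq2, and in edgeR Gpnmb passed without IgG replicate 14 (adjusted p = 0.0254) and Itgam without IgG replicate 20 (adjusted p = 0.0335). In the same libraries the adipocyte list had a median of 1.15 (adjusted p = 0.662 with an estimated correlation) and the contractile smooth muscle list a median of -0.58 (adjusted p = 0.673 with an estimated correlation).

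Lists on the matrix and its enzymes gave mixed values. Extracellular proteases and inhibitors had 17 of 24 members with negative values and a median of -0.20, with an adjusted p of 0.0605 (camera), and 2 members, Adam8 and Mmp12, were past the threshold. When adjusted over the list alone, 6 lower and 2 higher members passed. The list passed camera without IgG replicate 14 (median -0.26, adjusted p = 0.00597), and its median was -0.06 without IgG replicate 18 and -0.09 without IgG replicate 20. Oxidative stress and antioxidant genes had a median of -0.29 (adjusted p = 0.0576), and this list passed without IgG replicate 14 (-0.44, adjusted p = 0.00187), IgG replicate 18 (-0.18, adjusted p = 0.0317) or anti-CTHRC1 replicate 7 (-0.32, adjusted p = 0.0329). In that list Hmox1, the haem-degrading enzyme, fell from 147 ± 41.4 to 28.7 ± 3.04 CPM, and Ncf1, a subunit of the phagocyte NADPH oxidase, fell from 41.4 ± 6.05 to 17.1 ± 2.13 CPM. Fibrillar and associated collagens passed camera upward, with a median of 0.59, 14 of 17 positive values and an adjusted p of 0.00139 (adjusted p = 0.673 with an estimated correlation). The median was 0.35 without IgG replicate 18, and the adjusted p was 0.0494 without anti-CTHRC1 replicate 5. No collagen passed over all genes and 5 did when adjusted over the list alone. Col1a1 had a log2 fold change of 0.59 (SE 0.34, adjusted p = 0.419, edgeR) and Col3a1 of 0.45 (SE 0.29, adjusted p = 0.479, edgeR). Without IgG replicate 18 these were 0.34 and 0.23, and Col1a1 had 0.91 without IgG replicate 14. Eln, the elastin gene, was at 6968 ± 1365 against 15710 ± 5608 CPM, with a log2 fold change of -1.17 (SE 0.30, adjusted p = 0.165, edgeR, and adjusted p = 0.000412, DESeq2), and Lox had -0.65 (SE 0.23, adjusted p = 0.241, edgeR).

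Contractile smooth muscle genes had negative values in 20 of 20 members, with a median of -0.58 and an adjusted p of 0.000804 (camera), and 0.673 as the adjusted p with an estimated correlation. The median was -0.32 without IgG replicate 18 and -0.36 without anti-CTHRC1 replicate 7, and it was -0.85 without anti-CTHRC1 replicate 5. No member passed over all genes in edgeR or when adjusted over the list alone, and 3 had an unadjusted p under 0.05. Acta2, smooth muscle actin, was at 1726 ± 801 against 2702 ± 1100 CPM (adjusted p = 0.492, edgeR), Myh11 at 773 ± 321 against 1170 ± 533 CPM and Tagln at 673 ± 253 against 1129 ± 418 CPM. The log2 fold change of Acta2 was -0.65, and -0.33 without IgG replicate 18, -0.37 without anti-CTHRC1 replicate 7 and -1.06 without anti-CTHRC1 replicate 5. That of Myh11 was -0.60, and -0.30, -0.35 and -0.96 without the same libraries and -0.93 without IgG replicate 14. With the adipocyte list as a covariate they were 0.28 and 0.09 (adjusted p = 0.999 for both). TGF-beta ligands, receptors and target genes had a median of -0.41 with 14 of 20 negative, an adjusted p of 0.00532 (camera) and an adjusted p of 0.662 with an estimated correlation. Tgfb1 had -0.73 (SE 0.13, adjusted p = 0.0869, edgeR), and it passed in DESeq2 and, without IgG replicate 20, in edgeR (adjusted p = 0.0344). Without IgG replicate 20 the adjusted p of the TGF-beta list was 0.0508, with a median of -0.42.

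Genes of cardiac and skeletal muscle included the largest increases. Sln, which encodes the calcium-pump regulator sarcolipin, rose by 4.64 on the log2 scale (SE 0.51), from 0.32 ± 0.21 to 8.14 ± 1.88 CPM. Myl7, the atrial myosin light chain (chromosome 11, 5896637 to 5898782), rose by 4.24 (SE 0.39), and Myl4, another atrial light chain, rose by 2.52 (SE 0.19). Nppa, also on the muscle list, was at 2.19 to 19.2 CPM in the antibody libraries and 0.10 to 0.47 CPM in the IgG libraries (adjusted p = 0.0905, edgeR). Whether the aortas carried unequal amounts of heart muscle was not tested. The muscle list had 18 of 20 positive values and a median of 0.67, with an adjusted p of 0.000752 (camera) and an adjusted p of 0.673 with an estimated correlation. Members past the threshold numbered 2 over all genes and 4 when adjusted over the list alone. Without replicate 39 the list had a median of -0.15 and camera still called it upward (adjusted p = 0.0486), so the median and the test differed in sign, and without IgG replicate 20 the median was 0.44 and the adjusted p 0.107. The median was 2.08 without IgG replicate 14, 1.05 without anti-CTHRC1 replicate 7 and 0.37 without IgG replicate 18. The mean of the list was 4.97 log2 CPM in replicate 39 and 4.27 in IgG replicate 14, above 3.62 and 3.0 in anti-CTHRC1 replicates 7 and 5 and 2.42 and 1.35 in IgG replicates 18 and 20.

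Adipocyte markers had 16 of 16 positive values, with a median of 1.15 and an adjusted p of 5.44e-08 (camera), and an adjusted p of 0.662 with an estimated correlation. Lep, which encodes the adipocyte hormone leptin (chromosome 6, 29060220 to 29073877), rose from 6.0 ± 2.07 to 33.6 ± 9.96 CPM (adjusted p = 0.0412, edgeR), and it was the 1 member past the threshold over all genes, with 9 when adjusted over the list alone. Fatty acid oxidation and lipid metabolism genes had a median of 0.81 (adjusted p = 3.66e-05, and adjusted p = 0.673 with an estimated correlation), with 5 members past the threshold when adjusted over the list alone. Oxidative phosphorylation genes had 23 of 23 positive values and a median of 0.60 (adjusted p = 2.98e-06, and adjusted p = 0.673 with an estimated correlation). The groups overlapped in the mean of this list, with 6.59 log2 CPM in anti-CTHRC1 replicate 5 and 6.5 to 6.79 in the IgG libraries. Anti-CTHRC1 replicates 7 and 39 were at 7.63 and 7.29. Without anti-CTHRC1 replicate 7 the medians were 0.47 for the fatty acid list and 0.34 for oxidative phosphorylation. Brown adipocyte markers had a median of 0.74 (adjusted p = 0.0362, and adjusted p = 0.755 with an estimated correlation), and the adjusted p was 0.325 without anti-CTHRC1 replicate 7, with a median of 0.36, and 0.0956 without replicate 39, 0.107 without IgG replicate 14, 0.0522 without IgG replicate 18 and 0.0604 without IgG replicate 20. The mean of the brown list was 4.17 log2 CPM in anti-CTHRC1 replicate 5, below the 4.52 to 4.55 of the IgG libraries. It was 5.68 and 5.27 in anti-CTHRC1 replicates 7 and 39. Adventitial fibroblast markers had a median of 0.45 (adjusted p = 2.18e-05, camera), an adjusted p of 0.251 with an estimated correlation and 0.00856 in fry, which was the smallest in either test, and 9 of 15 members passed when adjusted over the list alone. Endoplasmic reticulum stress genes had a median of 0.36 (adjusted p = 0.0236, and adjusted p = 0.673 with an estimated correlation), with an adjusted p of 0.113 and a median of 0.19 without anti-CTHRC1 replicate 7, and of 0.0604 and 0.31 without IgG replicate 20. The mean of the stress list in anti-CTHRC1 replicate 5 (5.76 log2 CPM) lay within the 5.67 to 5.82 of the IgG libraries. Other genes that rose were Thbs4, a thrombospondin (2.66 on the log2 scale, SE 0.32), Aqp2, a water channel (3.07, SE 0.39), Tenm4 (1.80, SE 0.15), Orm1 (1.84, SE 0.18), Hcar2, the nicotinic acid receptor (1.49, SE 0.17), and Ebf2, a transcription factor of adipogenic precursors (1.39, SE 0.16).

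**Figure D2:**
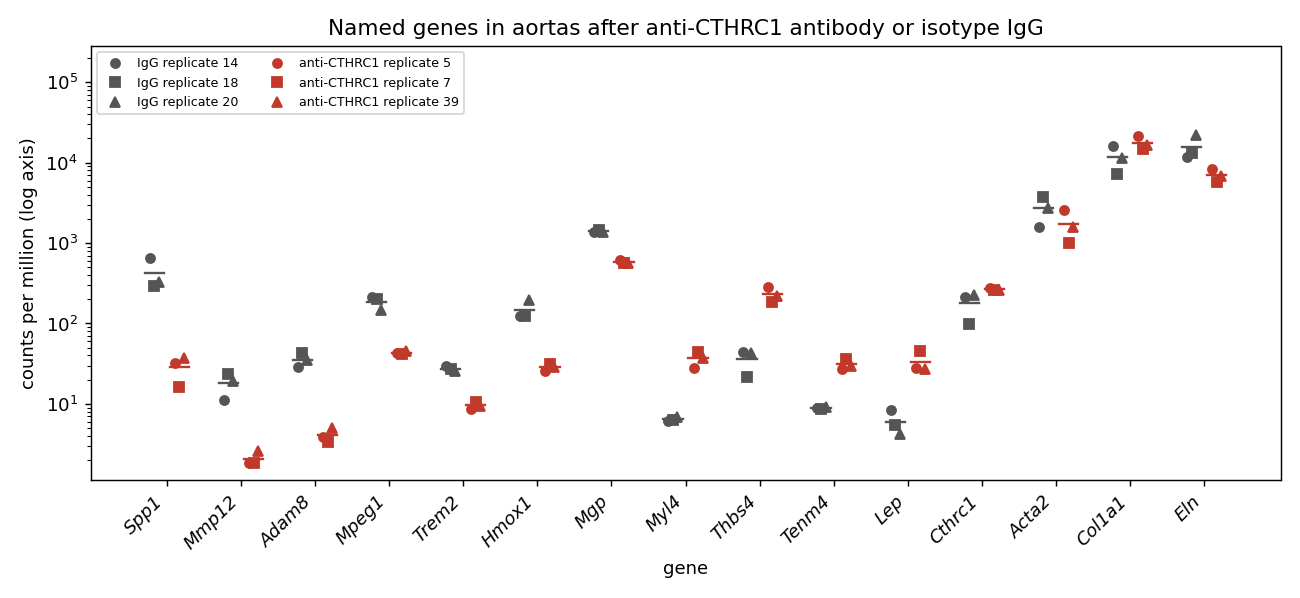
CPM on a log axis for named genes in the 6 libraries, grey for IgG and red for the anti-CTHRC1 antibody, with a bar at each group's mean and a point for each replicate. Spp1, Mmp12, Adam8, Mpeg1, Trem2, Hmox1 and Mgp lie lower in each antibody library, and Myl4, Thbs4, Tenm4 and Lep lie higher, while Cthrc1, Acta2, Col1a1 and Eln did not pass the threshold.

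T and NK cell markers had a median of -2.10 (adjusted p = 0.000539, and adjusted p = 0.673 with an estimated correlation), with list means of 1.29 and 2.04 log2 CPM in IgG replicates 14 and 18 and -1.14 in IgG replicate 20, below the antibody libraries, and the median was -1.35 without IgG replicate 18. Mesothelial markers had a median of -2.41 (adjusted p = 0.0236, and adjusted p = 0.703 with an estimated correlation), with a list mean of 3.30 in IgG replicate 18 and -1.47 in IgG replicate 20, and the adjusted p was 0.0542 without anti-CTHRC1 replicate 5, 0.107 without IgG replicate 14 and 0.158 without IgG replicate 18, where the median was -1.03. Cell cycle genes had a median of -0.95 (adjusted p = 0.000178, and adjusted p = 0.673 with an estimated correlation), and without IgG replicate 14 the median was -0.24 and the adjusted p 0.0607. Chondrocyte and osteogenic genes had a median of -0.62 (adjusted p = 0.00431, and adjusted p = 0.662 with an estimated correlation), with an adjusted p of 0.163 and a median of -0.59 without IgG replicate 14. In that list Mgp, an inhibitor of vascular calcification, fell from 1402 ± 46.8 to 580 ± 26.3 CPM (adjusted p = 0.0196, edgeR). Immediate early and handling stress genes had a median of -0.59 (adjusted p = 0.000149, and adjusted p = 0.673 with an estimated correlation), with a median of -0.34 without IgG replicate 18 and -0.39 without anti-CTHRC1 replicate 5. Its member Dusp1, a phosphatase of MAP kinases, fell by 0.79 (SE 0.09).

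**Figure D3:**
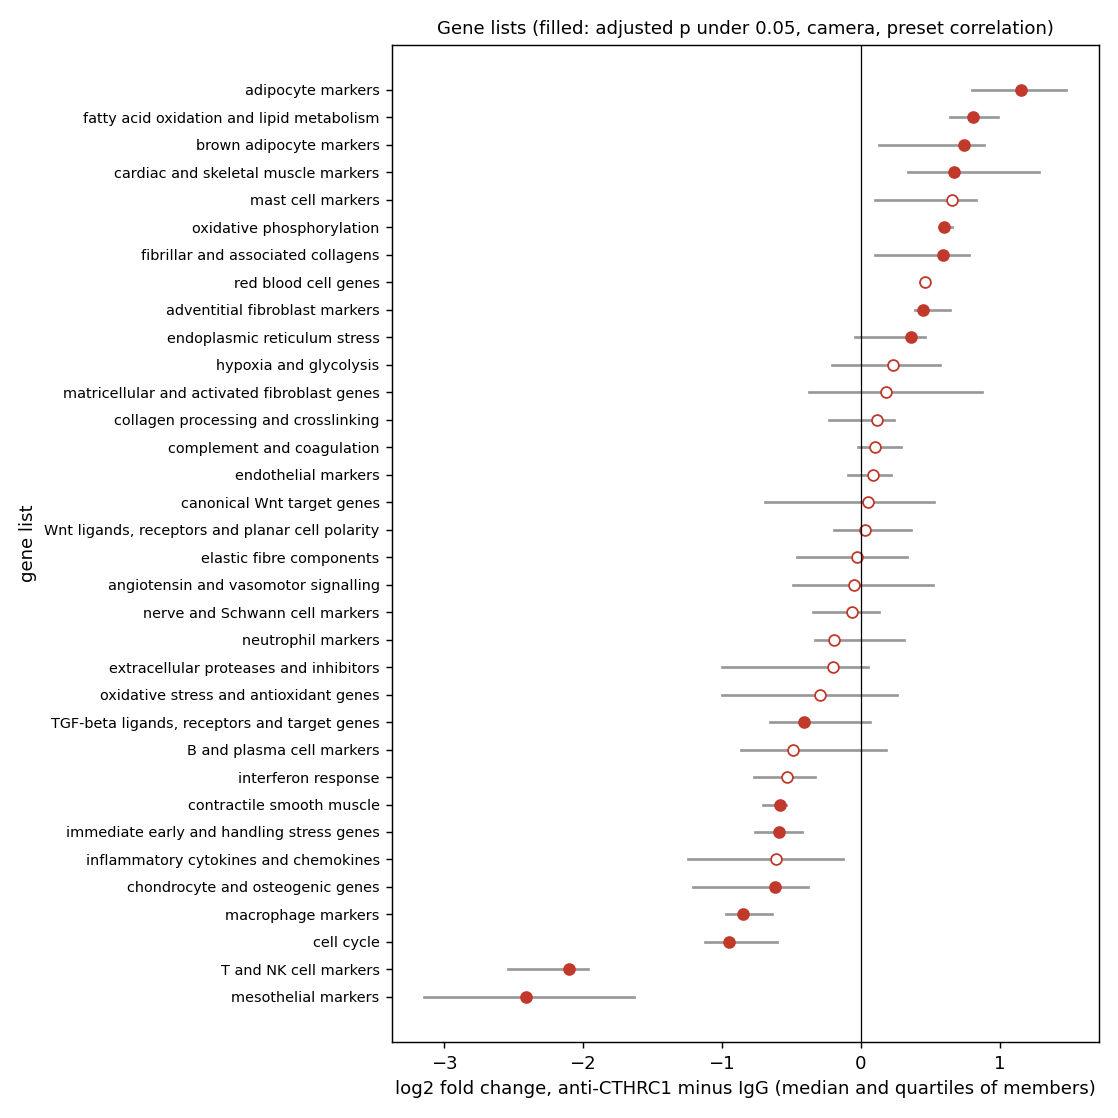
Median log2 fold change of the members of each of 34 gene lists (point) with the quartiles (line), anti-CTHRC1 antibody minus IgG. Filled points are the 16 lists with a camera adjusted p under 0.05 at a preset correlation, of which 8 were higher and 8 lower, and with an estimated correlation 0 lists passed.

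In the lists that did not pass camera on all 6 libraries, the medians were 0.12 for collagen processing and crosslinking (adjusted p = 0.274), -0.03 for elastic fibre components (0.570), 0.18 for matricellular and activated fibroblast genes (0.327), 0.03 for Wnt ligands, receptors and planar cell polarity (0.411) and 0.09 for endothelial markers (0.327). A median near 0 can hide members that moved in opposite directions. In the matricellular list, 4 higher and 3 lower members passed in edgeR when adjusted over the list alone. In the elastic fibre list, 0 higher and 1 lower passed likewise, and 2 higher and 5 lower had an unadjusted p under 0.05. Leaving out 1 library gave medians from 0.01 (anti-CTHRC1 replicate 5) and 0.02 (IgG replicate 18) to 0.20 (anti-CTHRC1 replicate 7 or IgG replicate 14) for collagen processing, and from -0.14 (anti-CTHRC1 replicate 5) to -0.02 (anti-CTHRC1 replicate 39) for elastic fibres. For the matricellular list, which holds Cthrc1, they were 0.0 without IgG replicate 18, 0.07 without anti-CTHRC1 replicate 5, 0.37 without IgG replicate 20 and 0.40 without IgG replicate 14. The endothelial list passed upward without IgG replicate 18 (0.14, adjusted p = 0.032), and its median was -0.07 without IgG replicate 14 and -0.01 without anti-CTHRC1 replicate 7. Canonical Wnt target genes had a median of 0.05 and a mean of -0.16 (adjusted p = 0.766). Without anti-CTHRC1 replicate 5 the median was -0.04 for the Wnt ligand and receptor list and -0.07 for the target genes. It was 0.11 and 0.34 without anti-CTHRC1 replicate 7 and 0.16 and 0.0 without IgG replicate 20, and the target genes had 0.28 without IgG replicate 14 and 0.32 without IgG replicate 18. Inflammatory cytokines and chemokines had a median of -0.61 (adjusted p = 0.134), interferon response genes -0.53 (0.118), and B and plasma cell markers -0.49 (0.327). These 3 depended on single libraries, with medians of -0.13, 0.17 and 0.30 without IgG replicate 14, so that the interferon and B cell values turned. The cytokine median was -0.38 without anti-CTHRC1 replicate 5 and -0.34 without IgG replicate 18, and the interferon median was -0.33 without anti-CTHRC1 replicate 5. Without IgG replicate 20 the cytokine list (-0.98, adjusted p = 0.000248) and the interferon list (-0.76, adjusted p = 7.24e-05) passed downward, as did the cytokine list without anti-CTHRC1 replicate 39 (-0.83, adjusted p = 0.0461) and the interferon list without anti-CTHRC1 replicate 7 (-0.66, adjusted p = 0.0329). Neutrophil markers had a median of -0.19 while camera gave an upward direction (adjusted p = 0.980), and the median was 0.10 without anti-CTHRC1 replicate 5 and 0.29 without IgG replicate 18. Camera turned downward for them without IgG replicate 14 or anti-CTHRC1 replicate 7 or 39 (medians -0.35, -0.23 and -0.38). Medians were 0.66 for mast cell markers (0.192), 0.46 for red blood cell genes (0.318), -0.06 for nerve and Schwann cell markers (0.806), 0.23 for hypoxia and glycolysis (0.190), 0.10 for complement and coagulation (0.142) and -0.05 for angiotensin and vasomotor signalling (0.933). Red blood cell genes passed without anti-CTHRC1 replicate 5 (0.82, adjusted p = 0.019) and without IgG replicate 18 (0.95, adjusted p = 0.0375) and had a median of -0.01 without anti-CTHRC1 replicate 7. Hypoxia and glycolysis passed without anti-CTHRC1 replicate 5 (0.38, adjusted p = 0.00551), and complement and coagulation without IgG replicate 18 (0.24, adjusted p = 0.0414). The hypoxia median was 0.13 without anti-CTHRC1 replicate 7 and 0.40 without IgG replicate 14. The nerve list had medians of 0.10 without IgG replicate 14 and 0.09 without IgG replicate 20, but -0.20 without IgG replicate 18 and -0.18 without anti-CTHRC1 replicate 39. The angiotensin list had 0.02 without anti-CTHRC1 replicate 39, 0.27 without IgG replicate 20 and -0.17 without IgG replicate 14. Of the genes fixed beforehand, Il6 had a log2 fold change of -2.47 (SE 0.65), Timp1 -1.14 (SE 0.36), Ccl2 -1.13 (SE 0.46), Mmp9 -0.87 (SE 0.43), Postn 0.84 (SE 0.33), Wnt5a 0.72 (SE 0.25), Ror2 0.60 (SE 0.26), Tnc 0.57 (SE 0.29), Cnn1 -0.58 (SE 0.51), Klf4 -0.44 (SE 0.38), Mmp2 0.21 (SE 0.13) and Fbn1 0.19 (SE 0.17), none past the threshold in edgeR, while Il6 (adjusted p = 0.00252) and Timp1 (adjusted p = 0.0113) passed in DESeq2. Without IgG replicate 14, Timp1 had -0.59, Mmp9 -0.23, Cnn1 -0.945 and Klf4 -0.74. Without IgG replicate 18, Il6 had -1.41, Ror2 0.355, Cnn1 -0.11, Klf4 0.05 and Fbn1 0.12. Without anti-CTHRC1 replicate 5, Wnt5a had 0.455, Tnc 0.29, Cnn1 -0.99, Klf4 -0.29 and Fbn1 0.04. Without anti-CTHRC1 replicate 7, Cnn1 had -0.31 and Fbn1 0.295, and without IgG replicate 20 Fbn1 had 0.286. With the adipocyte list as a covariate Cnn1 had 0.43.

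Of 303 KEGG terms in the deposited table with 10 to 300 tested genes, 59 passed camera, 26 higher and 33 lower. Higher terms were led by peroxisome (79 genes, median 0.44, adjusted p = 9.81e-09), propanoate metabolism (31 genes, median 0.74) and degradation of valine, leucine and isoleucine (52 genes, median 0.67). Lower terms were led by osteoclast differentiation (114 genes, median -0.32, adjusted p = 7.45e-06) and leishmaniasis (62 genes, median -0.54). With an estimated correlation 0 terms passed, and these leading terms had an adjusted p of 0.789.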

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

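No paired analysis was possible because the groups share no replicate numbers. Only 1 of the 10 splits of the 6 libraries gave as many calls, the real one with 61 and the highest other with 0, and 10 splits are too few for a share under 0.05. Every other split also parts anti-CTHRC1 replicate 39 from replicate 5 or 7, between which it lies. The splits therefore cannot tell an effect of the antibody from the likeness of these libraries. Alternatives added after the data were seen were limma on FPKM, the joint omission of 2 libraries, the covariate, DESeq2 and the gaps between lists with libraries left out, and the KEGG alternatives. Counts below are higher then lower, against 20 and 41. DESeq2 size factors, limma-voom, library sizes without mitochondrial and haemoglobin genes, a minimum log2 fold change of 1 and limma on FPKM stayed within 1.5 times both counts. No named gene past the threshold reversed in the settings run per gene, and the test's direction turned in no called list with DESeq2 size factors, an estimated correlation, fry or libraries left out, the settings run on lists, but the median of the muscle list went from 0.67 to -0.15 without anti-CTHRC1 replicate 39. DESeq2 gave 588 and 996, no filter 32 and 63, a mean of 5 CPM 32 and 66, and a threshold of 0.10 gave 88 and 146. Leaving out 1 replicate gave 0 to 71 higher and 0 to 156 lower in edgeR. Leaving out anti-CTHRC1 39 and IgG 14 gave 0 and 0 (2056 at an unadjusted p under 0.05), and the adipocyte covariate 0 and 0 (691 unadjusted). DESeq2 gave 1047 and 917 leaving out anti-CTHRC1 5, 318 and 612 leaving out 7, 212 and 520 leaving out 39, 935 and 947 leaving out IgG 14, 372 and 640 leaving out 18, 775 and 1731 leaving out 20, and 296 and 376 leaving out 39 and 14. All 61 genes were shared with DESeq2 on 6 libraries and with each single omission in DESeq2. The 61 were called on these same libraries and DESeq2 called 732 to 2506 genes in the omissions, so this sharing is no separate evidence. In edgeR, 0 of the 61 stayed without anti-CTHRC1 7, anti-CTHRC1 39 or IgG 18, and 1 without anti-CTHRC1 5. Without IgG 14 it was 59, and without IgG 20 it was 53. Of the 20 genes named by largest change, 0 to 20 passed when 1 replicate was left out, 0 without 39 and 14, and 0 with the covariate. Lists past the threshold were 16, with 0 at an estimated correlation and 1 in fry, and 14 to 18 when 1 replicate was left out. KEGG terms were 59, with 0 at an estimated correlation and 32 to 57 when 1 replicate was left out. Fewer libraries leave fewer degrees of freedom, but the cause was not tested. With 3 simulated libraries per group at the dispersion of these data, 37% of 2-fold changes were recovered, so smaller changes were often not detectable.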

Other observations

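The second glucocorticoid list and the liver, brain and olfactory receptor test were set before their results were seen, and the other tests were chosen after. Among called genes, Per1, Tsc22d3 and Dusp1 are induced by glucocorticoids. A first list of 8 such genes was chosen after these were seen and includes them, so it partly restates the calls. It had 8 of 8 negative values and a median of -1.51. A second list of 16 had 12 negative values, a median of -0.53 and an unadjusted camera p of 0.00657 (p = 0.255 with an estimated correlation), with 0 members past the edgeR threshold. Sgk1 had -1.68 (SE 0.34) and Ddit4 -1.93 (SE 0.26), while Angptl4 had 0.75 (SE 0.36). A lower glucocorticoid response in the antibody libraries is a hypothesis that met its test, a negative median (-0.53) and a camera p under 0.05. That bound used the preset correlation, at which 16 of the 34 lists passed, against 0 with an estimated one. Meeting it therefore decides little. On the second list, Mt1 (-1.57) and Mt2 (-2.2) were also members of the oxidative stress list. Hour of collection and handling, which could also move Per1 and the immediate early genes, were not tested.

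Anti-CTHRC1 replicate 39 may hold RNA or reads from the material of replicates 5 and 7. Its best mixture of 2 libraries left a residual 0.23 times the smallest of the other 5 libraries. That smallest one (0.1212) was replicate 7 fitted by replicate 39 with a 0% share of replicate 5. IgG replicate 20, fitted with a 36% share of replicate 39, left 0.1494. No other library was known to be intermediate, so the ratio does not decide against an independent aorta of intermediate composition. The 98 genes at 2-fold above both, 28 of them keratin or skeletal or cardiac muscle genes by symbol, argue against an exact average of the 2 columns. Immunoglobulin genes found in replicate 5 and nearly absent from 7 were in 39 at a pooled ratio of 0.42 to replicate 5, near the 39% share of other genes. That ratio separates poorly, since IgG replicate 14 had 0.28 over the same genes and 0.44 over the 9 variable segments alone, although 7 of the 9 segments lay between 0.2 and 0.6 in replicate 39 and 3 in IgG replicate 14. Whether material or reads were mixed stays open.

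In IgG replicate 14, testis RNA is a candidate source of part of the 288 genes, which hold 16 of the 28 listed germ cell genes. With a smaller constant added to each CPM than for the 288, 71.4% of the 28 were 4-fold or more above each other library. These were led by Smcp (75.1 CPM) and Ldhc (70.6 CPM), and 6 of 8 Leydig cell genes passed likewise. Odf2, however, was at 33.9 CPM or more in all 6 libraries. The 288 genes were led by the cartilage gene Col2a1 (351 CPM) and also held the ventricular genes Myl2 (95.8 CPM) and Myl3 (63.8 CPM), which are not on the germ cell or Leydig lists. IgG replicate 18 was the highest of the other libraries in 92.7% of the 288 genes, at a median of 11.61% of the IgG 14 level against 1.02% to 2.20% in the others. A smaller share of the same source would give this for most of the 288 genes, but Col2a1, Myl2 and Myl3 departed from it. Col2a1 was at 4.52 CPM in IgG replicate 18 and 3.73 CPM in IgG replicate 20. Myl2 (2.07 CPM) and Myl3 (2.48 CPM) in IgG replicate 18 lay below anti-CTHRC1 replicates 7 (9.38 and 7.91 CPM) and 39 (7.29 and 6.72 CPM). The background test set beforehand met its bound with a median log2 ratio of 1.16, but liver genes gave 2.53, brain genes 0.45 and the 3 detected olfactory receptor genes -0.98, and the summed 32.77 CPM of 216 olfactory receptor genes, the lowest of the 6 libraries, argues against genomic DNA. A median of -0.23 over weakly counted genes decides nothing, because it was -1.0 to -1.94 in the other libraries, so a broad background and RNA of further tissues stay open, while IgG 14 may account for most of the cell cycle value (median -0.24 without it against -0.95).

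Lower macrophage and higher adipocyte genes could reflect a changed share of perivascular fat. Equal lowering of other cell types would leave the gap between the macrophage list and another list alike in both groups. The macrophage minus endothelial gap differed by -0.82 (SE 0.33) with no overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows). It differed by -0.51 (SE 0.19) without IgG 14 and by -0.89 (SE 0.56), within 2 SE of 0, without IgG 18. The macrophage minus adventitial fibroblast gap differed by -1.19 (SE 0.19), and by -1.07 to -1.34 with no overlap when any 1 library was left out. Both gaps restate list values that were known when the gaps were chosen. They describe a departure from equal lowering and are no separate test of it. Fat with its own vessels and fibroblasts stays open, because the macrophage minus smooth muscle gap differed by -0.21 (SE 0.48) with overlap, fibroblasts of fat would widen the fibroblast gap too, the smooth muscle minus endothelial gap of -0.62 (SE 0.30) had no overlap but was -0.35 (SE 0.25) without anti-CTHRC1 7, and with 1 library left out the macrophage minus smooth muscle gap ran from -0.51 (anti-CTHRC1 7) to 0.10 (IgG 14) and 0.11 (anti-CTHRC1 5), each with overlap. With the adipocyte level as a covariate the macrophage list had a median of -0.64 against -0.85 and the 41 lower genes -1.41 against -1.52, and the calls ended as the median SE of the 41 went from 0.15 to 0.27. The adipocyte level itself ran from 8.42 to 9.24 log2 CPM in the antibody libraries and from 7.24 to 8.15 in the IgG libraries. This fit therefore cannot separate a changed share of fat from an effect of the antibody. A fall of lipid-associated beyond resident macrophage genes, -0.47 (SE 0.22) with overlap, was not decided, since only without anti-CTHRC1 5 (-0.54, SE 0.21) or IgG 18 (-0.66, SE 0.11) did the groups not overlap, and an effect of the antibody on macrophages stays open too.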
